A study of Mus musculus with 13 samples.

How the data were processed

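Drop-seq, which captures single cells with barcoded beads in droplets, was run on suprachiasmatic nuclei (SCN) of 8-week-old C57BL/6 mice. Per the labels, each library pooled 5 mice that had been kept in a 12 h light and 12 h dark cycle for 2 weeks and then in constant darkness. There were 12 dark libraries, 1 at each circadian time (CT) from CT14 to CT58 in steps of 4 h, and 1 library from mice given 1 h of light (250 lux) at CT18. Tissue was digested with papain for 45 min at 37 °C, passed through a 40 µm filter and loaded at 150 cells per µl, per the labels. The submitters' processing notes name bcl2fastq 2 for demultiplexing and STAR for alignment to GRCm38, with no STAR version. The deposited matrices of the 12 dark libraries hold UMI counts per gene and cell, in whole numbers. The deposited matrix of the light library holds signal in steps of 1.3037, of which 100% of its 2750550 values were whole multiples within a tolerance of 0.001. Its deposited sum, 5284521.9, equals the mean of the 12 dark totals. Dividing by that step recovered 4053454 UMIs. The recovered values were used for cell filters, clustering and alternatives. Because the unit differed from the one the design had assumed, the main test after light was limma on log2 CPM, which a constant scale does not alter, in place of edgeR.

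In all, 66317 cells had been deposited, 3767 to 6563 per library, each with at least 200 detected genes. Cells with at least 400 genes and at most 20% mitochondrial UMIs were kept, which removed 25436 and 10 cells. Scrublet (scanpy 1.11.5, scikit-image 0.26.0, expected rate 0.05, each library on its own) called 506 of the 40871 remaining cells as doublets, from 0.2% at CT18 to 1.98% at CT58. The other 40365 cells were clustered (2000 variable genes, 40 principal components, 20 neighbours, Leiden resolution 1, leidenalg 0.10.2) after 712 genes had been left out, namely the gene lists named here except neighbouring hypothalamus, and ribosomal, mitochondrial and haemoglobin genes. Clusters were named from marker lists. A marker counted when it was 1.5-fold higher than in all other cells, with 10 CPM added, and had a UMI in at least 5% of cells, and a name needed at least 3 markers. Neurons were clustered again, and a cluster with at least 5 of 11 SCN markers was called SCN-like. A neuron cluster with at least 2 glial markers among its 10 top genes was left unnamed. A class was tested when it had at least 20 cells in the light library and in at least 10 dark libraries. SCN-like neurons were further split with 1500 variable genes, 30 components and resolution 0.6, leaving out 1291 genes, of which 656 were those called rhythmic in the class.

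UMIs were summed per class and library. Genes with a mean of at least 10 UMIs per library were tested, which is 120 summed over the dark libraries or 130 over all. Rhythms were fitted to the 12 dark libraries with edgeR 4.0.16 (R 4.3.3, TMM scaling, robust quasi-likelihood F-test of a 24 h cosine, 9 residual degrees of freedom). Amplitude is given on the log2 scale from the middle of the curve to its peak, with its standard error (SE), and the fold is the fitted peak over the fitted trough. Peak times are folded to 24 h. A Pearson correlation of the 6 times between the first cycle (CT14 to CT34) and the second (CT38 to CT58) is given as a measure of repeat. For called genes it is not independent of the call, since the cosine was fitted to both cycles. The light library, whose collection time the labels do not give, was placed at CT19 and compared with the cosine through the dark libraries in limma 3.58.1 (trend, robust) on log2 CPM with a pseudocount worth 2 UMIs at the mean library size, 2.58 CPM in SCN-like neurons. Differences between classes, or between a subcluster and the remaining SCN-like neurons, were tested with the library as a block (edgeR for rhythm, limma for light), with both depths as they were and after thinning the deeper sum to the shallower one. Adjusted p values are Benjamini-Hochberg over all genes tested in a class, with a threshold of 0.05. Shares of cells over circadian time were tested with 100000 permutations of the times. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used elsewhere.

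The 14 gene lists were fixed before the data were examined, as were the comparisons, the filters and the rule for naming genes. They cover the core clock (25 genes), SCN peptides and receptors (20), immediate early genes (48), heat shock (20), cold inducible genes (4), glucocorticoid responsive genes (20), endoplasmic reticulum chaperones (18), cholesterol synthesis (23), membrane excitability (28), the secretory pathway (14), mitochondrial encoded genes (13), sex (5), blood (5) and neighbouring hypothalamus (19). Over circadian time a list was compared with all other tested genes by Fisher's exact test, adjusted over the lists of a class. That test takes genes as independent, so its p values are too small where members of a list move together. No repeat with an estimated correlation was run for it. After light, camera with a preset correlation of 0.01 was used and repeated with an estimated correlation. Named genes were, for rhythm in SCN-like neurons, all members of the clock and peptide lists and the 20 largest amplitudes among called genes whose cycles correlated above 0.5. In other classes they were called clock genes and the 10 largest amplitudes. After light they were the 15 largest rises and 10 largest falls outside the range of the 12 dark libraries, with the immediate early and clock lists. Every list added 2 to 4 members. Of 193 named genes, 192 were found in the GENCODE vM21 annotation of GRCm38.

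Each fit was tested on simulated data with the real gene means and library sizes and 200 changed genes. Genes were drawn independently, without a shift shared by the genes of a library. With times dealt at random over the real libraries, up to 197 genes were called in SCN-like neurons. The shares of false calls below can therefore be too low for these data. In SCN-like neurons 54% of rhythms of log2 amplitude 0.5 and 99% of those of 1 were recovered over 9142 genes, and 2.55% of the calls were false. For light over 9118 genes, 94.7% of log2 rises of 2 were recovered with 1.15% false calls, and 83.9% of falls of that size with 16.2% false calls. No paired analysis was possible because there was 1 light library and the replicate numbers only follow the order of deposition. Each time point is 1 pool, so the spread around the fitted curve is the only replicate error, and the light library is assumed to vary like the dark ones. Intervals of shares are exact Clopper-Pearson 95% intervals and, like the floor of 3 UMIs for genes at 0, cover counting error only. In subclusters, a gene rose by share of cells when its interval after light lay above every dark library. Cells and not libraries gave that interval, so the spread between libraries was left out. Alternatives covered scaling, test, filters, doublets, covariates, curve shape, the placing of the light library, pseudocount, depth and each dark library left out in turn. Smooth muscle cells, tanycytes, perivascular macrophages, vascular leptomeningeal cells, unnamed neurons and an unnamed dividing cluster were too few or unnamed, and their rhythms and light changes were not analysed here. Some genes are not reported here.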

Results

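The SCN, the paired hypothalamic nucleus that times daily rhythms, was sampled as single cells at 12 circadian times in constant darkness, from CT14 to CT58, and once after a 1 h light pulse given at CT18. The 12 dark libraries held 3464718 to 7478342 UMIs and the light library 4053454, with a median of 522 to 810.0 UMIs per deposited cell. There were no replicate libraries at any time, so matched times of the 2 cycles are the nearest to a repeat. The series asks which genes cycle in which cell types of the SCN and which respond to light at night, as far as its labels state.

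Among 40365 cells, 7420 (18.38%) were SCN-like neurons, named from markers such as Six6, Lhx1, Vipr2 and Nms. One of their clusters had Cck, Prokr2 and Vipr2 among its top genes, another Avpr1a, Nms and Rorb, another Vip and Grp, and another C1ql3, Rasl11b and Prok2. Of the last cluster, whose 3 named genes peaked between CT3.83 and CT8.38, 28.24% of cells came from CT54. There were also 8120 other neurons, 7791 oligodendrocytes (Mog, Mag), 3421 ependymal cells (Ccdc153), 3347 oligodendrocyte precursors (Pdgfra), 2980 astrocytes (Agt, Gja1), 2071 endothelial cells (Cldn5), 1150 microglia (C1qa, Cx3cr1), 819 pericytes (Kcnj8) and 572 newly formed oligodendrocytes (Enpp6, Gpr17). The pericyte cluster had 6 of 6 pericyte markers raised, but also 9 of 9 endothelial and 5 of 5 smooth muscle markers. Endothelial signal in its sums can therefore not be set apart. SCN-like neurons made up 18.1% ± 7.61 (SD, n = 12) of the dark libraries, from 7.03% at CT30 to 34.4% at CT18, and 478 of 2352 cells (20.3%, 95% interval 18.71 to 22.01) after light. The share of none of the 10 classes changed with circadian time in a permutation test (adjusted p from 0.766 to 0.846, none with an unadjusted p under 0.05). The CT18 library stood apart, with the most Oxt, a neuropeptide of neighbouring magnocellular neurons (4289 CPM against 110.4 at CT14), and summed markers of neighbouring hypothalamus of 4723 CPM against 651.0 CPM at CT38, the lowest. Free RNA was measurable, since Avp, made by neurons, reached 4795 CPM in SCN-like neurons and also 103.1 CPM in astrocytes and 59.9 CPM in oligodendrocytes.

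In SCN-like neurons the molecular clock ran with its feedback arms in separate phases through both dark cycles. Dbp, a clock output transcription factor, rose 8.59-fold from trough to peak (log2 amplitude 1.55 ± 0.10, SE over 12 libraries) with a peak at CT4.68. Per1 (5.97-fold, CT4.58), Nr1d1 (REV-ERB alpha, 5.31-fold, CT2.51), Nr1d2 (7.60-fold, CT4.92), Ciart (12.4-fold, CT4.67) and Tef (5.11-fold, CT5.83) peaked in the early subjective day. Per2, a repressor of the clock, followed at CT8.34 with 17.5-fold (adjusted p = 2.03e-13) and Cry1 at CT10.61 with 3.48-fold. Arntl (BMAL1), the activator that drives them, peaked at CT14.56 with 2.38-fold (log2 amplitude 0.63 ± 0.11), and Nfil3 at CT17.06 with 3.64-fold. Of 23 core clock genes tested, 16 cycled (18 adjusted over the list alone, mean peak CT5.97, adjusted p = 8.86e-13 against other genes). Clock (log2 amplitude 0.19, adjusted p = 0.367), Cry2 (0.17, 0.634) and Csnk1e (0.30, 0.0521) did not pass. Rorb passed with 1.93-fold but kept its call in 10 of 12 fits that left out 1 library, lost without CT14 or CT18.

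**Figure D1:**
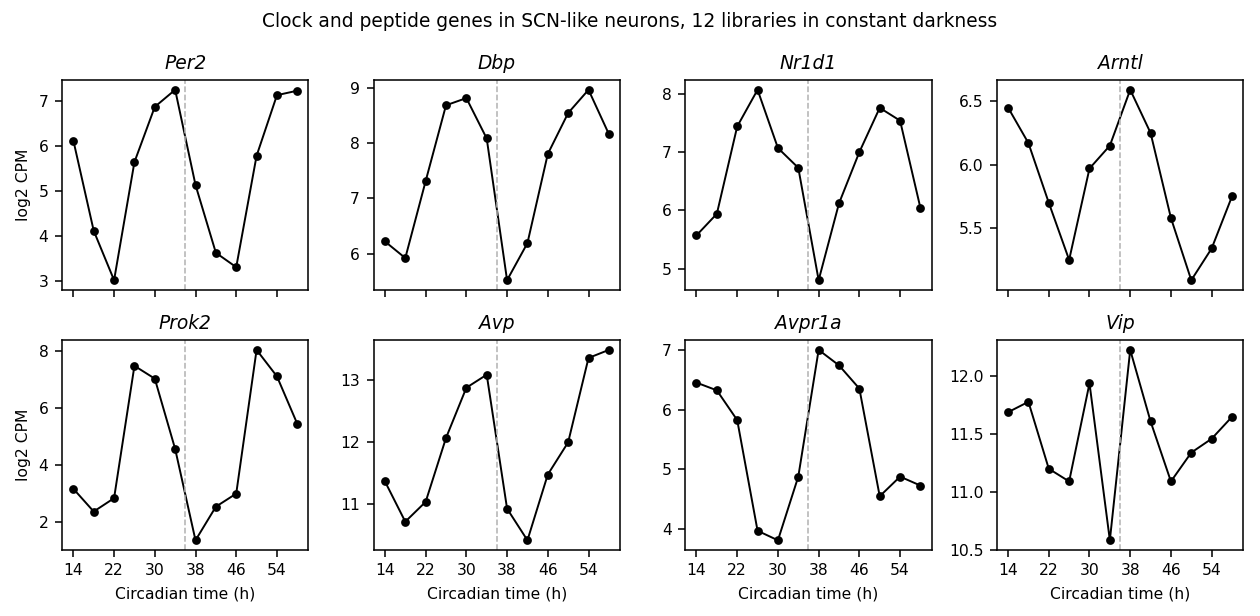
Log2 CPM of 8 genes in SCN-like neurons at each of the 12 circadian times in constant darkness. Straight lines join the times, and a dashed line lies between the cycles. Per2, Dbp and Nr1d1 peak in the subjective day of both cycles and Arntl early in the subjective night, and Vip did not pass the test.

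Of 14 peptide and receptor genes of the SCN 6 cycled, 5 with peaks in the subjective day. Prok2, a secreted output signal of the SCN, had the largest amplitude of the named genes (log2 3.55 ± 0.46, fitted 137.3-fold, peak CT4.24, adjusted p = 0.000379). It went from 0 UMIs at CT38 and 3 at CT18 to 135 at CT26 and 125 at CT50, so that its fitted fold rests on a trough near the floor. That of Ciart does too, with 0 UMIs at CT38, 3 at CT18 and 41 at most, at CT54. Rgs16, a regulator of G protein signalling, rose 8.04-fold with a peak at CT4.25, and Avp (vasopressin) 6.81-fold at CT6.99. Its receptor Avpr1a was in antiphase, 6.61-fold with a peak at CT17.08. C1ql3 peaked at CT8.38 with 6.21-fold, and Calb2, at 1.54-fold, kept its call in 6 of 12 fits without 1 library. The list was called more often than other genes (7 adjusted over the list alone, adjusted p = 0.000567). Vip (log2 amplitude 0.27, adjusted p = 0.629), Grp (0.45, 0.22), Cck (0.43, 0.475), Scg2 (0.09, 0.664), Penk (0.12, 0.918), Grpr (0.20, 0.804), Bdnf (0.82, 0.23) and Calb1 (0.26, 0.108) did not pass.

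Of 31 immediate early genes, which neurons induce with activity, 10 cycled (15 adjusted over the list alone, mean peak CT4.72, adjusted p = 0.000105), led by Fosl2, an AP-1 subunit (13.7-fold, CT3.27), Dusp4, a MAP kinase phosphatase (9.93-fold, CT4.31), and Vgf, a neuropeptide precursor (6.30-fold, CT6.66). Of the 10, 8 peaked between CT3.20 and CT8.34, Rasd1 at CT15.01 and Klf6 at CT21.40. Per1 and Per2, the latter at CT8.34, are among the 10 and are also counted in the core clock list. Secretory genes had 5 of 14 called (10 adjusted over the list alone, mean peak CT7.06, adjusted p = 0.0038). Among them Chga, a dense core vesicle protein, changed 2.99-fold with a peak at CT7.89 and Pcsk1, a prohormone convertase, 3.10-fold at CT6.48. Membrane excitability genes had 3 of 21 called (5 adjusted over the list alone, adjusted p = 0.263). Kcnc2, a fast potassium channel, peaked in the day at CT9.05 with 2.37-fold, and Kcnma1, the BK channel, at night at CT19.65 with 1.92-fold.

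Among protein folding and lipid genes, called heat shock genes peaked together near CT17.51, with 10 of 17 called (12 adjusted over the list alone, adjusted p = 2.9e-07), among them the chaperones and co-chaperones Dnajb1 (2.87-fold, CT16.18), Hsph1 (2.41-fold, CT17.74) and Chordc1 (2.34-fold, CT17.39). Cholesterol synthesis genes peaked at CT19.14 on average, with 9 of 20 called (13 adjusted over the list alone, adjusted p = 1.37e-05) and Msmo1, a sterol oxidase, at 3.27-fold. Endoplasmic reticulum chaperones had 10 of 18 called (13 adjusted over the list alone, adjusted p = 4.08e-07), spread from Herpud1 at CT7.22 over Xbp1, a transcription factor of the unfolded protein response, at CT11.21 to Sdf2l1 at CT16.07. The cold inducible RNA binding genes Rbm3 (3.92-fold, CT7.57) and Cirbp (1.75-fold, CT5.54) peaked in the day and Sfpq at night (CT16.14), 3 of 4 called both over all genes and adjusted over the list alone (adjusted p = 0.00278). Cirbp lost its call without CT54. Of 10 glucocorticoid responsive genes, Cdkn1a (CT14.59) and Ddit4 (CT18.91) cycled (2 adjusted over the list alone, adjusted p = 0.246). None of 7 mitochondrial, 4 sex, 4 blood and 2 neighbouring hypothalamus genes was called by edgeR. Adjusted over the list alone 4 blood genes passed and none of the other 3 lists. Hba-a1, a haemoglobin of red cells, had a log2 amplitude of 2.65 and an adjusted p of 0.131 over all genes.

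In total 656 of 9142 genes cycled in SCN-like neurons (7.18%, 1866 with an unadjusted p under 0.05, median log2 amplitude 0.51), of which 584 correlated above 0.5 between the cycles. That correlation is not independent of the call, since the cosine was fitted to both cycles. The peaks of the 656 genes were spread over the day, with 163, 172, 145 and 176 genes in successive windows of 6 h from CT0. Large amplitudes beside those named belonged to Rasl11b, a small GTPase (23.5-fold, CT3.83), Dkk2, a WNT antagonist (16.8-fold, CT5.94), Lgi2 (9.46-fold, CT20.47), Mtcl1 (7.86-fold, CT4.45), Strip2 (7.69-fold, CT8.6) and Pter (7.83-fold, CT8.17). Iltifb (15.4-fold, CT18.31) and Il22 (8.14-fold, CT18.09), near-identical copies of a cytokine gene, shared a night peak, and reads cannot be assigned to 1 of them with certainty. DESeq2 called 582 genes. The count was 476 to 662 with any 1 library left out and 435, of which 409 were among the 656, without CT18 and CT38.

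Glial, vascular and ependymal cells also had clocks, and these peaked later. Dbp peaked at CT8.69 in oligodendrocyte precursors, CT8.89 in astrocytes, CT9.6 in pericytes (63.1-fold), CT9.71 in ependymal cells (27.0-fold), CT9.88 in endothelial cells (54.8-fold) and CT12.01 in oligodendrocytes (4.55-fold). That is 4.01 ± 0.45 h to 7.33 ± 0.61 h (SE) after SCN-like neurons. Core clock genes were called in ependymal cells (9 of 19, 13 adjusted over the list alone, mean peak CT10.52), astrocytes (6 of 16, 11, CT9.64), oligodendrocytes (6 of 15, 8, CT12.55), endothelial cells (4 of 11, 5, CT10.9), precursors (4 of 16, 7, CT9.2) and pericytes (3 of 6, 4, CT10.26). Examples with their folds were Nr1d1 in ependymal cells (11.8-fold, CT6.99) and astrocytes (3.27-fold, CT7.22), Per1 in oligodendrocytes (3.74-fold, CT11.69), Tef in endothelial cells (6.75-fold, CT11.56) and Nr1d2 in pericytes (13.1-fold, CT10.54). In astrocytes Nr1d1 and Usp2 lost their calls without CT34, Per1 without CT14 or CT34, Per3 without CT22 or CT34 and Tef without CT22, CT34 or CT46. In precursors Nr1d1 and Per3 each kept theirs in 7 of 12 such fits, and in pericytes Hlf lost its call without CT34. Bhlhe40 in ependymal cells kept its call in 5 and Bhlhe41 in oligodendrocytes in 6 of 12. Other neurons had 0 of 22 clock genes called by edgeR (0 adjusted over the list alone, Dbp log2 amplitude 0.21, adjusted p = 0.808) and microglia 0 of 3 (0 adjusted over the list alone), and none was tested in newly formed oligodendrocytes.

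**Figure D2:**
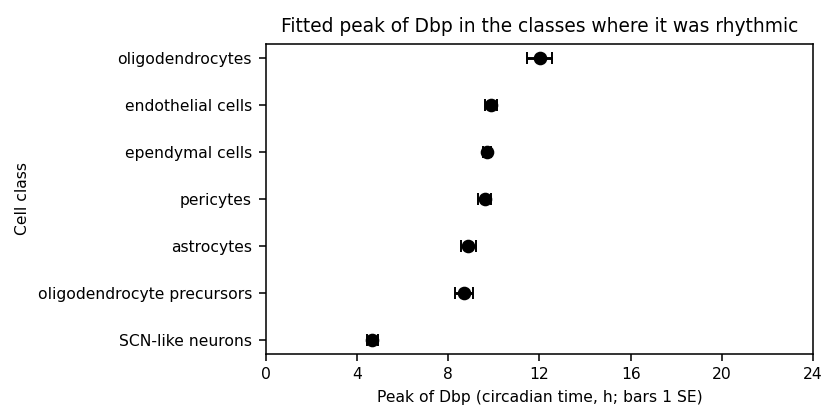
Peak circadian time of Dbp, in hours, with its standard error, in the 7 cell classes where it was called. SCN-like neurons peak at CT4.68 and the other classes between CT8.69 and CT12.01.

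The differences of rhythm themselves were tested against 3 classes. Against other neurons 587 of 9007 genes differed (1606 with an unadjusted p under 0.05), 550 of them with the larger amplitude in SCN-like neurons, among them 14 of 22 clock genes such as Dbp (adjusted p = 3.04e-20), Per2 (1.41e-07) and Arntl (0.0132). Against astrocytes 115 of 3402 genes differed (498 unadjusted), 61 larger in SCN-like neurons and 53 in astrocytes, including Dbp (adjusted p = 2.6e-10), Per1 (6.53e-09) and 6 other clock genes of 16. Against oligodendrocytes 313 of 6678 genes differed (1178 unadjusted), with 10 of 15 clock genes. After the sums were thinned to equal totals 441, 68 and 252 genes differed.

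By Fisher's test, which takes genes as independent, heat shock genes also cycled more often than other genes in 5 further classes, with peaks in the night. Called members numbered 9 of 20 in ependymal cells (17 adjusted over the list alone, mean peak CT19.24, adjusted p = 8.84e-11), 9 of 17 in oligodendrocytes (15, CT17.69, 7.38e-12), 4 of 18 in endothelial cells (11, CT18.19, 0.00209), 2 of 15 in astrocytes (4, CT18.04, 0.0222) and 2 of 9 in pericytes (5, CT18.49, 0.0265). In astrocytes Hspa8 kept its call in 8 of 12 fits without 1 library and Hsph1 in 8 of 11. In other neurons 1 of 18 was called (7 adjusted over the list alone), Chordc1, the only gene called in that class, so that the list cannot be set against other genes. The list did not pass in microglia (1 of 7, 3 adjusted over the list alone, adjusted p = 0.123), precursors (1 of 15, 5 alone, 0.11) or newly formed oligodendrocytes (0 of 11 by edgeR, 4 alone). Hsp90ab1, a major cytosolic chaperone, peaked between CT18.21 and CT18.89 in endothelial cells, pericytes, oligodendrocytes, microglia and precursors, with 1.72- to 2.55-fold, and at CT19.82 in ependymal cells with 2.50-fold. Its call was lost without CT30 in pericytes, precursors and microglia, and without CT42 in microglia. Cirbp peaked in the day, at CT5.69 in precursors (3.54-fold), CT6.52 in ependymal cells (2.63-fold) and CT7.09 in astrocytes (3.55-fold). Over all cells, the summed heat shock level ran from 7713 CPM at CT30 to 12140 CPM at CT18 in the dark.

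**Figure D3:**
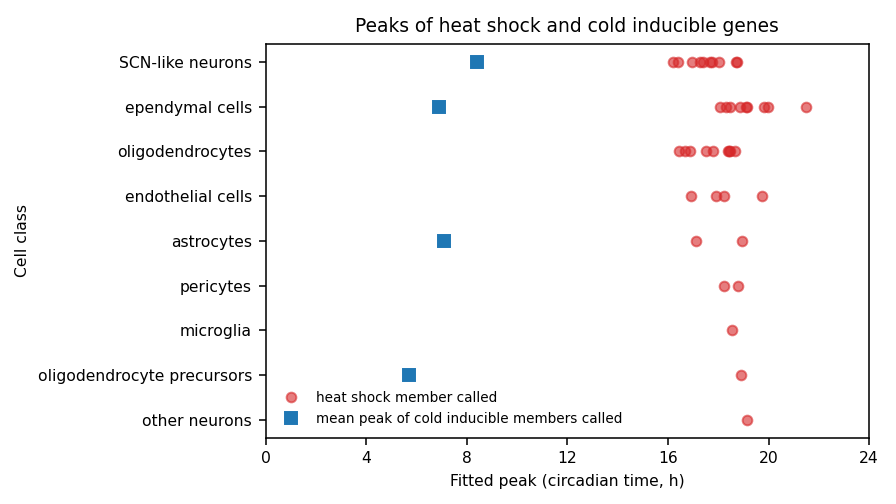
Peak circadian time, in hours, of each called heat shock gene per cell class (red points) and the mean peak of called cold inducible genes (blue squares, 4 classes). Heat shock genes lie in the subjective night and the cold inducible means between CT5.69 and CT8.41.

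By the same Fisher's test, glucocorticoid responsive genes cycled more often than other genes in oligodendrocytes, endothelial cells, astrocytes and ependymal cells. In oligodendrocytes 6 of 14 such genes cycled (11 adjusted over the list alone, mean peak CT13.07, adjusted p = 1.72e-07), led by Sgk1, a kinase induced by glucocorticoids (log2 amplitude 2.07, 17.7-fold, CT12.56), and Zbtb16 (10.4-fold), which kept its call in 8 of 12 fits without 1 library. In endothelial cells 5 of 10 cycled (7 adjusted over the list alone, CT12.57, adjusted p = 1.21e-05), with Tsc22d3 (GILZ) at 4.70-fold and Ddit4 at 4.21-fold. Tsc22d3 also peaked at CT11.89 in pericytes (4.60-fold, 1 of 7 genes, 1 alone, adjusted p = 0.302), CT12.82 in ependymal cells (5.38-fold, 2 of 8 genes, 6 alone, adjusted p = 0.0248) and CT12.51 in astrocytes (4.11-fold, 2 of 8 genes, 3 alone, adjusted p = 0.00917, the calls of Tsc22d3 and Nfkbia kept in 7 and 2 of 12 fits). In ependymal cells the other called gene, Cdkn1a, peaked at CT0.27, nearly in antiphase. Endoplasmic reticulum chaperones were called in precursors (5 of 17, 13 adjusted over the list alone, mean peak CT17.06, adjusted p = 2.2e-08). With 1 library left out, Pdia3 kept its call in 4 of 12 fits, Creld2 and Sdf2l1 in 10 and Calr in 11. Class genes outside the lists included Fabp7, a fatty acid binding protein of astrocytes (4.97-fold, CT0.37), and Tspan4, a tetraspanin, in endothelial (4.25-fold, CT9.61), ependymal (10.4-fold, CT11.22) and pericyte (6.82-fold, CT9.81) sums. Timp3, an inhibitor of matrix proteases, peaked in pericytes at CT13.61 with 3.31-fold.

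By class, edgeR called 120 of 6999 genes in ependymal cells, 111 of 7522 in oligodendrocytes, 64 of 2965 in endothelial cells, 27 of 3828 in astrocytes, 19 of 5493 in precursors and 18 of 1475 in pericytes. It called 2 of 1245 in microglia (Hsp90ab1 and Ecscr), 1 of 11032 in other neurons (Chordc1, 2.25-fold, CT19.15) and 0 of 1218 in newly formed oligodendrocytes, where 48 had an unadjusted p under 0.05 and DESeq2 called 0. In other neurons 731 had an unadjusted p under 0.05 and DESeq2 called 11. Several of these counts rested on single libraries, and the lowest were 76 in ependymal cells without CT54, 57 in oligodendrocytes without CT54, 37 in endothelial cells without CT14, 11 in astrocytes without CT34, 8 in precursors without CT14 and 7 in pericytes without CT30 or CT34.

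In the light library a set of activity and clock genes lay above the dark curve in SCN-like neurons. There is 1 light library, and with each of the 13 libraries taken in turn as the lone one, the dark library CT38 called 145 genes against 28 for light, so that a property of the library cannot be told from light by these counts. In SCN-like neurons the CT38 calls, made by limma, were mostly falls, and edgeR did not make them. The median log2 change of immediate early genes was -0.35 with CT38 as the lone library. Among dark libraries it was at most 0.73, at CT26, and with the light library it was 0.91. The labels give a 1 h pulse at CT18 but no collection time, so the dark curve was read at CT19, an assumption that every change below rests on. Rrad, a small GTPase induced by calcium signalling, was 30-fold above the dark curve (log2 4.91 ± 0.55, SE from the fit to 12 dark libraries and 1 light library, adjusted p = 4.54e-06), with 331 UMIs after light. Fosl2 was 24.6-fold higher (log2 4.62 ± 0.60, adjusted p = 0.000312), Srxn1, an antioxidant enzyme, 8.01-fold (log2 3.00 ± 0.32, adjusted p = 3.1e-06) and Nptx1, a secreted synaptic protein, 8.39-fold (log2 3.07 ± 0.58, adjusted p = 0.007). Per2 rose 6.76-fold (log2 2.76 ± 0.38, adjusted p = 0.000237) to a level inside its own daily range, as did Vgf (3.98-fold) and Rora (2.99-fold). Dusp4 (6.67-fold), Midn (5.74-fold), Homer1, a postsynaptic scaffold (5.36-fold), Ezr (4.11-fold), Traf3ip1 (3.87-fold), Dnajb5 (3.73-fold), Nr4a3, an orphan nuclear receptor (3.38-fold), Kdm6b, a histone demethylase (3.00-fold), and Spty2d1 (2.84-fold) rose above every dark library. The noncoding transcript 1700016P03Rik (9.45-fold) and the protein-coding Gm13889 (4.74-fold) did so too. Rora, Nr4a3 and Spty2d1 each kept the call in 7 of 12 fits that left out 1 dark library. With at least 800 genes per cell none of these 3 nor Vgf passed. The highest adjusted p in those fits was 0.0894 for Rora, 0.0817 for Nr4a3 and 0.074 for Spty2d1, and CT18 was among the libraries whose removal ended each call.

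Of 32 immediate early genes 7 rose (10 adjusted over the list alone), namely Rrad, Fosl2, Per2, Dusp4, Homer1, Vgf and Nr4a3, and 28 lay above the dark curve (median log2 change 0.91). The list was higher by camera (adjusted p = 2.07e-17, adjusted p = 0.182 with an estimated correlation). The classical activity markers did not pass, with log2 changes of -0.37 for Fos (adjusted p = 0.973), -0.45 for Fosb, -1.12 for Npas4, 0.99 for Egr1, 1.85 for Junb, 2.07 for Nr4a1 and 1.85 ± 1.01 for Per1 (adjusted p = 0.829). Fos ran in the dark at 313.2 to 1582 CPM over all cells against 910.2 CPM after light. With that spread in the dark, the test cannot show that light left Fos unchanged. Of 23 core clock genes Per2 and Rora rose (2 adjusted over the list alone, camera adjusted p = 0.0183, adjusted p = 0.422 with an estimated correlation).

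Of 9118 genes 22 rose and 6 fell (625 with an unadjusted p under 0.05), and 16 of the rises and all 6 falls lay outside the range of the 12 dark libraries. The called rises outside the named rule were Nnat, Peg10, Slc6a17 and Hmgb1, listed here after their values were seen. The falls were 4 genes with pseudogene-type names and Chpf2 and B3galt6, enzymes of glycosaminoglycan synthesis. Gm13009 and Gm9703 had 0 UMIs after light, and their 95% counting intervals reached ratios of 0.265 and 0.244 to the 12 dark libraries summed. Set at a floor of 3 UMIs, they would be 4.68-fold and 5.09-fold lower. Gm19244 had 3 UMIs, a ratio of 0.0963 (95% counting interval 0.0198 to 0.284), and Rps15a-ps3 had 1, a ratio of 0.0899 (0.00226 to 0.509). Chpf2 fell to a ratio of 0.238 (0.118 to 0.429) and B3galt6 to 0.401 (0.218 to 0.680). Rps15a-ps3 kept its call in 7 of 12 fits without 1 library, and B3galt6 lost it without CT42. The pseudogene-type genes were low in the light library in other cells too, with a median log2 deviation of -2.83 from the dark median outside SCN-like neurons, and 16.2% of called falls were false in simulated data. Gm13009 was the least low there, at -1.69 against -1.35 at CT18 in the dark. Its light response also differed between SCN-like neurons and other neurons. With edgeR on the recovered UMIs 54 genes rose and 5 fell, and with DESeq2 49 and 2. All 22 rises were among those of each tool, but 4 of the 6 falls were among those of edgeR and 1, Gm19244, among those of DESeq2.

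After light, none of 14 peptide genes (2 adjusted over the list alone), 17 heat shock (4), 4 cold inducible (0), 10 glucocorticoid responsive (1), 18 endoplasmic reticulum chaperone (0), 20 cholesterol synthesis (0), 21 excitability (0), 14 secretory (2), 7 mitochondrial (0), 4 sex (0), 4 blood (0) and 2 neighbouring hypothalamus genes (0) passed over all genes in limma. By camera the peptide list was higher (adjusted p = 0.042, adjusted p = 0.205 with an estimated correlation), as were heat shock (0.0183, adjusted p = 0.422 with an estimated correlation) and secretory genes (0.0183, adjusted p = 0.182 with an estimated correlation). Blood genes were lower (0.0355, adjusted p = 0.422 with an estimated correlation). Hsp90aa1 was at log2 0.63 (adjusted p = 0.103). The summed heat shock level over all cells was 13350 CPM after light, above the highest dark library at 12140 CPM.

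In the remaining 9 classes limma called 3 genes, all lower after light. They were Golgb1, a Golgi protein, in microglia (2 UMIs, ratio 0.12, 0.0145 to 0.44), and Gria2, a glutamate receptor subunit (5 UMIs, ratio 0.22, 0.0711 to 0.518), and Fam207a (2 UMIs, ratio 0.138, 0.0166 to 0.502) in oligodendrocytes. Fam207a kept its call in 6 of 12 fits without 1 library, Gria2 in 8 and Golgb1 in 10, and none of the 3 passed with edgeR, DESeq2 or a pseudocount of 8 UMIs. In simulated data 24.1% of called falls in oligodendrocytes were false, and 2.11% in microglia. Other neurons had 0 of 10950 genes called by limma, with 857 at an unadjusted p under 0.05 and 0 called by edgeR or DESeq2. In ependymal cells 0 of 6928 were called (466 unadjusted, 0 by edgeR or DESeq2), in astrocytes 0 of 3748 (130, 0), in precursors 0 of 5453 (236, 0), in pericytes 0 of 1431 (84, 0), in newly formed oligodendrocytes 0 of 1217 (33, 0) and in endothelial cells 0 of 2961 (129, 0 by DESeq2 and 1, Ptgds, by edgeR). By camera, immediate early genes were lower in ependymal cells (adjusted p = 0.00204, adjusted p = 0.964 with an estimated correlation), endothelial cells (0.00319, adjusted p = 0.656 with an estimated correlation) and pericytes (1.29e-07, adjusted p = 0.991 with an estimated correlation). Blood genes were lower (2.88e-09, adjusted p = 0.1 with an estimated correlation, 3 of 4 adjusted over the list alone) and glucocorticoid responsive genes higher (0.0405, adjusted p = 0.495 with an estimated correlation) in endothelial cells, and core clock genes higher in astrocytes (0.0364, adjusted p = 0.918 with an estimated correlation).

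The light response of SCN-like neurons differed from that of other neurons in 20 of 8973 genes (596 with an unadjusted p under 0.05), 15 of them larger in SCN-like neurons. These included Srxn1 (log2 difference 2.63 ± 0.36, adjusted p = 4.35e-05), Rora (1.63 ± 0.22), Fosl2 (3.69 ± 0.67), Nptx1 (3.23 ± 0.59) and Rrad (4.45 ± 0.85). After the sums were thinned to equal totals 12 genes differed. Against astrocytes 0 of 3331 genes differed by limma (154 unadjusted) and against oligodendrocytes 2 of 6625, Irs2 and Fam207a (424 unadjusted, 1 after thinning), but 4 and 12 of the 28 genes called in SCN-like neurons were tested there, against 25 for other neurons.

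Within SCN-like neurons most called genes lay in the Vip and Grp group. Without rhythmic genes the class split into subcluster 1 (Cck, Prokr2 and Vipr2, 3146 cells, median 849.5 UMIs), subcluster 2 (Mef2c, Bcl11b, Ppp1r17 and Avp, 2216 cells, 1642 UMIs), subcluster 3 (Grp, Vip and Cd24a, 1688 cells, 1267.5 UMIs) and subcluster 4 (Bdnf and Onecut3, 370 cells, not tested). The first and second also differed in depth. In subcluster 3, which held 97 cells after light, 66 of 4162 genes rose and 34 fell (494 with an unadjusted p under 0.05), against 103 and 16 with edgeR, and 16.8% of called falls there were false in simulated data. Rrad rose by log2 5.51, Fosl2 by 5.31, Srxn1 by 4.83, Prok2 by 4.11, Vgf by 4.03, Nr4a3 by 2.90 and Per1 by 2.35. The median log2 change of immediate early genes in subcluster 3 was 0.873 with the light library. It was higher with the dark libraries CT14 (1.19), CT26 (1.17) and CT54 (1.06), so this median does not set light apart there. In subcluster 1 it was 0.341 with light against 0.781 with CT14, and in subcluster 2 0.646 against 0.764 with CT26. Of 21 immediate early genes 5 rose (6 adjusted over the list alone, with Coq10b). In subcluster 1 only Per2 of 4733 genes was called (log2 2.66, 178 unadjusted, 10 genes by edgeR, 1 of 22 immediate early genes adjusted over the list alone), and not without CT30, CT54 or CT58. In subcluster 2, 0 of 6067 were called by limma (304 unadjusted, 11 by edgeR, 3 immediate early genes adjusted over the list alone, Fosl2, Junb and Per2).

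The difference between subcluster 3 and the remaining SCN-like neurons passed for 36 of 4136 genes (342 with an unadjusted p under 0.05), among them Srxn1 (log2 difference 3.44), Vgf (2.94), Irs2 (2.19) and Dclk1 (1.97). It did not pass for Fosl2 (2.59, adjusted p = 0.571), Nr4a3 (2.54, adjusted p = 0.122) or Per1 (1.34, adjusted p = 0.435), and Rrad was not tested for it. Adjusted over the list alone, Vgf and Nr4a3 passed among 19 immediate early genes. For subcluster 1 it passed for 0 of 4733 genes by limma (152 unadjusted) and for subcluster 2 for 0 of 6041 (221 unadjusted). With the sums thinned to equal totals, 19 genes differed for subcluster 3.

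Sums of each tested subcluster of SCN-like neurons held rhythmic clock genes, with slightly different fitted peaks. Membership varied between libraries. Subcluster 1 made up 26.3% of SCN-like neurons at CT34 and 55.5% at CT18, and subcluster 2 made up 52.5% and 17.6%. The median UMIs per SCN-like neuron there were 1887.5 and 836. Whether this moved the fitted peaks was not tested. EdgeR called 406 of 4759 genes in subcluster 1, 322 of 6090 in subcluster 2 and 111 of 4217 in subcluster 3, with 11 of 17, 14 of 19 and 10 of 16 core clock genes. Dbp peaked at CT5.45 ± 0.25 in subcluster 1, CT4.20 ± 0.30 in subcluster 2 and CT3.07 ± 0.39 in subcluster 3 (SE in h), and Per1 at CT5.62, CT4.10 and CT2.24. The rhythm of subcluster 3 differed from that of the remaining SCN-like neurons for 30 of 4192 genes, among them Dbp (adjusted p = 0.000868) and Per1 (0.0121). Subcluster 1 differed for 38 of 4759 genes, among them Dbp (adjusted p = 3.2e-05), Nr1d1, Per1, Rora and Tef, and subcluster 2 for 26 of 6062, with Nr1d1 as the clock gene among them (adjusted p = 0.0369). Vip, the marker peptide of subcluster 3, had a log2 amplitude of 0.33 there (adjusted p = 0.0619).

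**Figure D4:**
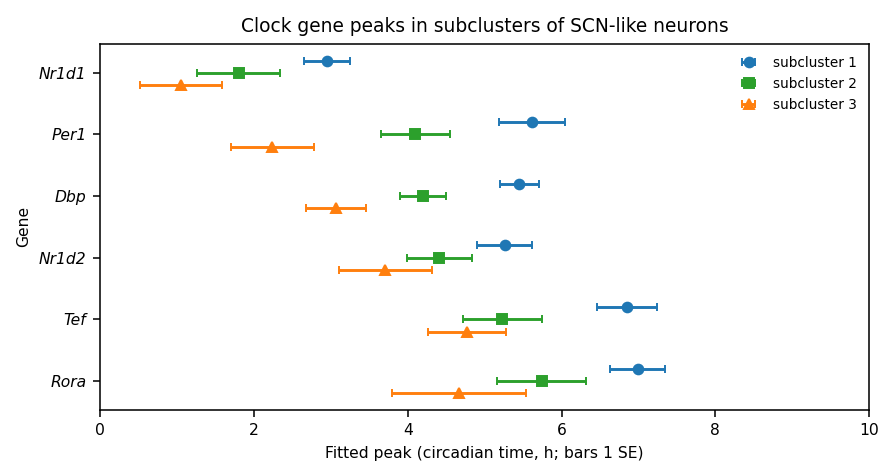
Peak circadian time, in hours, of Nr1d1, Per1, Dbp, Nr1d2, Tef and Rora in subclusters 1, 2 and 3 of the SCN-like neurons. All 6 genes peak earliest in subcluster 3.

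Positions on GRCm38, from the annotation, are chromosome 1 from 91415982 to 91459324 for Per2, chromosome 11 from 69095217 to 69109960 for Per1, chromosome 7 from 45705088 to 45710203 for Dbp, and chromosome 7 from 113207465 to 113314126 for Arntl. Nr1d1 lies on chromosome 11 from 98767932 to 98775333, Avp on chromosome 2 from 130580620 to 130582554, Prok2 on chromosome 6 from 99711299 to 99726392 and Vip on chromosome 10 from 5639218 to 5647617. Rrad lies on chromosome 8 from 104628070 to 104631327, Fosl2 on chromosome 5 from 32135801 to 32157842, Srxn1 on chromosome 2 from 152105516 to 152111376 and Sgk1 on chromosome 10 from 21882184 to 21999903. All are annotated as protein-coding genes.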

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

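The results in this part were marked because a tested difference between groups of cells passed. Tests written before their result were the breadth over pseudogenes, the correlation of heat shock genes between cycles, the thinning for Dbp and the 6 dealings of times for subclusters, and all others were chosen after the result had been seen.

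Rhythm differed between SCN-like neurons and other neurons for 587 genes, astrocytes for 115 and oligodendrocytes for 313. With the 12 times dealt anew 100 times, the real order included, 1 dealing reached each of these counts, the real one. The highest others were 70, 12 and 52. Chance is therefore unlikely, though 100 dealings cannot show a share below 1 of 100. Response to light differed between SCN-like neurons and other neurons for 20 genes, between SCN-like neurons and oligodendrocytes for 2 and between subcluster 3 and the remaining SCN-like neurons for 36. Rhythm differed from the remaining SCN-like neurons for 38 genes in subcluster 1, 26 in subcluster 2 and 30 in subcluster 3, each reached by 1 dealing of 100, the real one, with highest others of 11, 12 and 8.

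Of the counts of rhythmic genes, 1 dealing of 100, the real one, reached the count in SCN-like neurons (656, highest other 197), astrocytes (27, 22), endothelial cells (64, 21), ependymal cells (120, 80), oligodendrocytes (111, 105) and pericytes (18, 13). The same held for subcluster 1 (406, highest other 94), subcluster 2 (322, 86) and subcluster 3 (111, 30), and in oligodendrocyte precursors 2 of 100 did (19, highest other 34). Chance cannot be excluded for other neurons (13 of 100, highest other 83) and microglia (13 of 100, highest other 10). In newly formed oligodendrocytes the count was 0, which all 100 dealings reach by construction, so that nothing was tested there. For light, 13 lone libraries are too few to exclude chance. In SCN-like neurons 2 of the 13 called at least as many genes as the light library did, itself included. The other was CT38, whose calls were mostly falls, so a library without light can reach that number by limma. With CT38 as the lone library, edgeR made none of these calls in SCN-like neurons. CT38 also held the fewest SCN-like neurons (178) and UMIs (276334), and whether depth gave its limma calls was not tested. In subcluster 3 the light library called 100 genes, 1 of 13 reached that and the highest other was 41. In subcluster 1 it called 1, against 427 for CT38 and 5 each for CT30 and CT50, and in subcluster 2 it called 0, against 86 for CT38 and 37 for CT30.

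Of the 6 genes lower in the light library, 4 have pseudogene-type names. Their median deviation was also -2.83 log2 units in cells outside SCN-like neurons, against -0.51 as the lowest of the dark libraries, which argues against a response limited to SCN-like neurons. For Gm13009 alone this is less clear, at -1.69 against -1.35 at CT18, and its light response differed between SCN-like neurons and other neurons. Of 854 other processed pseudogenes 13% lay over 1 log2 unit below the dark median in the light library, against 0.586% to 5.15% in dark libraries and 0.762% of protein-coding genes, so that alignment or counting that differed between files is a candidate explanation, while the 2 shallower dark libraries, at 0.76, argue against depth. For Chpf2 the deviation outside SCN-like neurons was -0.30, which argues against such a difference of files, and for B3galt6, at -0.54, the test cannot tell. A response to light in all cell types was not tested and stays open for the pseudogene-type genes (-2.83).

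Heat shock genes peaked near CT18 in several classes. Handling that differed between libraries and not with time is argued against by a median correlation of 0.609 between cycles. That median was taken over 147 tests of a gene in a class, which share the same 6 pairs of libraries. Class medians ran from 0.858 in ependymal cells down to 0.464 in precursors, 0.368 in astrocytes and -0.104 in microglia. In precursors, astrocytes and microglia such handling is not argued against. Free RNA from SCN-like neurons is argued against in the 2 classes looked at, oligodendrocytes and ependymal cells, by a range at least 81.1 times that which Avp levels allow, and was not tested in the other classes. As a hypothesis, a daily cycle, such as that of body temperature, could raise heat shock and lower cold inducible transcripts, and the smallest gap between their mean peaks was 9.1 h, though in SCN-like neurons Sfpq, a called cold inducible gene, peaked at CT16.14, near the heat shock mean of CT17.51, and in precursors the gap rests on 1 gene of each list, so that this explanation stays open. Handling that varied with the time of day stays open, since no library of another handling was tested (median correlation 0.609).

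Dbp peaked later outside SCN-like neurons. Free RNA is argued against by a smallest lag of 4.01 h, since RNA from SCN-like neurons would carry their peak. Lower depth of the sums is argued against by the adjusted p of the difference of rhythm after thinning, 2.16e-11 as the larger of astrocytes and oligodendrocytes. As a hypothesis, the clocks of these classes may run later than that of SCN-like neurons (4.01 h), and whether the mixture of cell states within a class shifts its mean peak stays open and was not tested.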

How the results depend on the processing

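Of 338 gene values over circadian time, 7125 alternative fits left 6775 calls the same, 302 weaker and 48 stronger, and of 310 gene values after light, 8153 left 8035 the same, 88 weaker and 30 stronger. A gene not called in the main fit that stayed uncalled also counted as the same. These numbers therefore do not measure how stable the called genes were. Of 115 list tests after light 12 were called, and all 12 lost the call with an estimated correlation, while the other 103 stayed uncalled. All 20 alternatives for 10 shares were the same. No direction reversed. No paired analysis was possible because the groups share only replicate number 1. The setting of at least 800 genes was not run for astrocytes, endothelial cells, microglia, newly formed oligodendrocytes and pericytes, for rhythm or light. Leaving out CT18 and CT38, the pseudocounts, the harmonics of the dark curve, edgeR for light, and leave-one-out and thinned sums for subclusters were chosen after seeing the data. Where no cause is named, the cause was not tested.

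For rhythmic genes, DESeq2 called 11 in other neurons and 5 in microglia. With no filter (more genes tested) the counts were 38 in other neurons, 51 in astrocytes, 21 in microglia, 10 in newly formed oligodendrocytes, 30 in precursors, 203 in oligodendrocytes, 31 in pericytes and 645 over the 9 classes outside SCN-like neurons. With a mean count of 30 (fewer genes) they were 15 in astrocytes, 37 in endothelial cells, 1 in microglia, 6 in precursors and 7 in pericytes. With at least 800 genes (fewer cells) they were 10 in precursors, 41 in oligodendrocytes and 157 over the other classes. With median UMIs as a covariate they were 2 in other neurons, 7 in astrocytes, 41 in endothelial cells and 71 in oligodendrocytes. With 24 h and 12 h harmonics they were 153 in other neurons, 45 in astrocytes, 411 in ependymal cells, 11 in microglia, 7 in newly formed oligodendrocytes, 77 in precursors, 305 in oligodendrocytes and 1116 over the other classes. With 6 circadian times as a factor they were 114 in other neurons, 365 in ependymal cells, 15 in microglia, 4 in newly formed oligodendrocytes, 70 in precursors, 262 in oligodendrocytes and 959 over the other classes. Without CT18 and CT38 they were 435 in SCN-like neurons, 10 in precursors and 54 in oligodendrocytes. Thinned, the rhythm of 68 genes differed from astrocytes.

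After light, edgeR called 54 rises and 59 genes in SCN-like neurons and 1 in the other classes, and DESeq2 49 rises, 2 falls, 51 genes and 0. With no filter there were 57 rises, 66 genes and 1106 in the other classes, and with a mean count of 30, 14 rises, 3 falls, 17 genes and 1. Against CT18 and CT42 only there were 253 rises, 99 falls, 352 genes and 276. A pseudocount of 0.5 UMI called 8 in the other classes and one of 8 UMIs 3 falls and 0 in the other classes. Harmonics of the dark curve gave 39 rises, 44 genes and 32. Thinned, the response differed from other neurons for 12 genes, from oligodendrocytes for 1 and between subcluster 3 and the rest for 19. By share of cells with a UMI at 1000 UMIs, 0, 3 and 16 immediate early genes rose in subclusters 1, 2 and 3, and edgeR called 10 genes in subcluster 1 and 11 in subcluster 2, 2 of them immediate early. With an estimated correlation 0 lists passed in SCN-like neurons, astrocytes, endothelial cells, ependymal cells and pericytes.

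With 1 dark library left out, rhythmic genes ranged from 476 to 662 in SCN-like neurons, 1 to 3 in other neurons (2 without CT14 or CT50, 3 without CT22), 11 to 35 in astrocytes (11 without CT34), 37 to 78 in endothelial cells (37 without CT14), 76 to 156 in ependymal cells (76 without CT54) and 0 to 8 in microglia (0 without CT30 or CT42, 1 without CT14, CT18, CT22 or CT54, 5 without CT26, 8 without CT38). They ranged from 0 to 1 in newly formed oligodendrocytes (1 without CT18, CT50, CT54 or CT58), 8 to 28 in precursors (8 without CT14, 12 without CT38), 57 to 152 in oligodendrocytes (66 without CT14 or CT26, 58 without CT38, 57 without CT54), 7 to 25 in pericytes (7 without CT30 or CT34, 9 without CT54) and 230 to 447 over the other classes (230 without CT54). After light there were 20 to 32 rises, 4 to 9 falls and 25 to 39 genes in SCN-like neurons, and 1 to 18 in the other classes (1 without CT26, CT30 or CT54, 6 without CT22, 7 without CT50, 18 without CT46). Subcluster 1 had 0 to 1 immediate early rises (0 without CT30, CT54 or CT58), 0 to 3 genes (2 without CT18, CT42 or CT46, 3 without CT38 or CT50) and 0 to 1 differing (1 without CT38). Subcluster 2 had 0 to 1, 0 to 2 (2 without CT38, 1 without CT46) and 0 to 1, the first and last 1 without CT38, and subcluster 3 had 4 to 6, 73 to 119 and 26 to 49. In data simulated at the depth and number of these libraries, 54% of true rhythms at the smaller size and 99% at the larger were recovered in SCN-like neurons.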

Other observations

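The values in this part were chosen after the main results had been seen.

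In neurons outside the tested groups, the lower counting bound after light lay above every dark library for none of 8 genes looked at. In 105 unnamed neurons after light Rrad had 3 UMIs (32.4 CPM, highest dark library 44.3 CPM) and Srxn1 7 (75.5 CPM, highest dark library 100.7 CPM). In the 32 light cells of subcluster 4, Homer1 had 3 UMIs (58.9 CPM, lower bound 12.2 CPM), above its highest dark library of 57.6 CPM, Srxn1 had 5 UMIs (98.2 CPM, highest dark library 110.0 CPM) and Fos 40 (785.9 CPM, highest dark library 1669 CPM).

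Marker levels over all cells of a library also differed. Xist, the transcript of the inactive X chromosome, was at most 0.797 CPM in any library, and Ddx3y, a gene of the Y chromosome, lay between 154.3 and 210.2 CPM in dark libraries and at 187.8 CPM after light. Pomc and Npy, peptides of the arcuate nucleus, were at 15.8 CPM and 17.0 CPM in the light library, below the lowest dark values of 18.2 CPM and 19.5 CPM. Summed blood genes ran from 50.9 to 930.3 CPM in dark libraries, with 377.6 CPM after light. Tanycytes, 157 cells, came to 52.87% from CT14. Avp was as high in other neurons, at 4938 CPM, as in SCN-like neurons, at 4795 CPM.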
